A study of Macaca mulatta and Homo sapiens with 8 samples.

How the data were processed

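Single-cell RNA sequencing was carried out on dissociated parathyroid tissue from 4 rhesus macaques with normal glands and from 4 human parathyroid adenomas. Per the labels, 2 adenomas were mainly of chief cells and 2 mainly of oxyphil cells by histology. Each sample is a separate animal or donor with 1 droplet library. Per the labels' protocols, human tissue was dissociated mechanically and cleared of red cells by lysis, and collagenase is also named; the macaque protocol is incomplete in the labels. The deposited values are raw UMI counts per gene and barcode, in filtered matrices whose file headers name Cell Ranger. The submitters' processing notes name Cell Ranger 6.0.1 and the builds Mmul_10 and GRCh38. Per the file headers, version 6.0.1 made the macaque and chief matrices and version 3.0.2 both oxyphil matrices, so the software version and the histology cannot be told apart. The barcode sets also differ between the macaque and human libraries, while the labels name 1 chemistry for all, so any difference in chemistry would be confounded with species. The human files hold 33538 genes and the macaque files 35432, of which 11898 carry no symbol. The 16046 symbols that occur once in both annotations were used across species. Gene positions are from the GENCODE annotation of GRCh38; no macaque coordinates were used.

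Libraries held 7293257 to 44784165 UMIs in 42009 barcodes, each with at least 500 UMIs. Barcodes with at least 300 genes and at most 50% of UMIs from the 13 mitochondrially encoded mRNAs were kept. Doublets were scored with Scrublet (scanpy 1.11.5), and since its automatic threshold marked few barcodes, the highest scores were removed in each sample at an expected rate of 0.8% per 1000 barcodes, 1920 in all. This left 37972 cells, 27885 from macaques and 10087 from adenomas. Cells were clustered within each sample (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1). A cluster took the name of a class when at least 3 and at least 50% of that class's markers were raised by a log2 fold of 1 (pseudocount 20 CPM), or, for parathyroid-like, at least 3 of a set of markers that includes PTH, GCM2, CASR, CHGA and GATA3 against cells of other classes. The naming thresholds were set on the data; the markers of 17 classes (parathyroid, endothelial, lymphatic endothelial, mural, fibroblast, T or NK, B or plasma, myeloid, neutrophil, mast, thyroid follicular, C cell, thymic epithelial, thymocyte, adipocyte, erythroid, and Schwann or neural) were fixed before the data were examined. Clusters with parathyroid markers whose median depth was far under their sample's were kept apart, and clusters led by another class's markers stayed unnamed. No cell annotation by the authors was used here.

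UMI counts were summed per sample over parathyroid-like cells (1197346 to 34634859 UMIs per sample). Comparisons of all genes used edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and the quasi-likelihood test, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The comparisons were oxyphil against chief adenomas (human genes), adenomas against macaques, and PTH-high against PTH-low cells within macaques, within adenomas and as an interaction of the range with species. PTH-high and PTH-low cells were equal-sized groups from the top and the bottom of each sample's parathyroid-like cells, each holding 1 of every 3 cells, ranked by PTH UMIs over the UMIs of all genes other than PTH and the mitochondrially encoded ones, with sample as a block and PTH left out of the counts; both groups come from the same animal or adenoma, which is where the pairing comes from. They are ranges, not cell types, with the remaining cells between them. The mitochondrial transcript share is the percent of UMIs other than PTH that fall in the 13 mitochondrially encoded mRNAs. Single values per sample were compared with exact permutation tests, two-sided, in a family of 10 tests adjusted by Benjamini-Hochberg (scipy 1.17.1). The smallest two-sided p is 0.0286 for 4 samples against 4, 0.333 for 2 against 2, 0.125 for sign flips over 4 samples and 0.00781 over 8.

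Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) over each comparison's log CPM, repeated with an estimated correlation, and with fry; lists with fewer than 3 measured members were not tested. The 22 lists, fixed at the same time as the markers, were mitochondrially encoded mRNAs; nuclear genes of respiratory complex I, of complexes II and III, of complex IV and of complex V; the TCA cycle; mitochondrial biogenesis; glycolysis and hypoxia; parathyroid identity and hormone secretion; calcium, vitamin D and phosphate sensing; parathyroid tumour genes; the unfolded protein response and ER secretion; dissociation and immediate early response; cytosolic ribosomal proteins; cell cycle; angiogenic ligands; antigen presentation; interferon response; metallothioneins and antioxidant genes; cholesterol and lipid synthesis; iron handling; and lysosome and autophagy. Adjusted p-values of lists are from camera with the preset correlation unless said otherwise. Named genes were the 8 with the largest rise and the 8 with the largest fall among called genes with an average log2 CPM of at least 5 and complete separation of the samples or pairs, a fixed set of genes that includes PTH, GCM2, CASR, GATA3, CHGA, VDR, CCND1, RARRES2, PPARGC1A and VEGFA, and up to 4 examples of each list that passed. Groups with no UMIs of a gene give folds as lower bounds, set at 3 UMIs over the group; groups with 1 to 3 UMIs give a ratio with its 95% counting interval. Intervals and floors cover counting error only.

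The steps were tested on simulated data drawn from the samples' own means and library sizes, with 200 genes changed by known folds. At a 4-fold change the test found 4.48% of changed genes in oxyphil against chief adenomas and 80.6% in adenomas against macaques, and at 16-fold 75.8% and 100%. At a 2-fold change it found 97.0% over the macaque PTH range, 91.0% over the adenoma range and 80.6% for the interaction. The changed genes were drawn from the more abundant ones only, and the ranking of cells by PTH was not simulated. These rates therefore do not cover sparse genes. Replicates of 1 group were checked against each other; their summed counts differed by more than sampling noise (chi-square per degree of freedom of 45.1 to 469) and none were identical. Alternatives tried were DESeq2 1.42.0 size factors and its Wald test, no count filter, mitochondrial genes left out, mitochondrial limits of 20% and none, at least 1000 UMIs, doublets kept, Leiden resolution 0.5, all cells without classes, other groupings of the samples, count splitting, PTH over all UMIs, all cells split at the median in place of outer ranges, no replicate block, and leaving out each sample in turn. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs. Y-linked genes were left out before fitting, and X-inactivation transcripts were left out of the gene tables. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9 were used.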

Results

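The data are single-cell transcript counts from 4 normal rhesus macaque parathyroid glands and 4 human parathyroid adenomas, each a separate animal or donor. By the histology in the labels, 2 adenomas were mainly of chief cells, the hormone-secreting main cell of the gland, and 2 mainly of oxyphil cells, a larger cell rich in mitochondria. Macaque replicates 1 to 4 held 22918922, 40386350, 38220694 and 44784165 UMIs. Chief replicates 1 and 2 held 18147701 and 11691513 UMIs, and oxyphil replicates 1 and 2 held 25365582 and 7293257. After filtering, 37972 cells remained, with 1576 to 9084 per sample and a median depth of 1358 to 7175 UMIs per cell. The comparisons ask, from the series title and labels, how transcription differs between oxyphil and chief adenomas, between adenomas and normal glands, and across the range of PTH transcript content among the parathyroid cells themselves.

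Parathyroid-like cells made up most of each macaque gland and a smaller, more variable part of the adenomas. The parathyroid-like share of cells was 73.4% ± 1.84 in macaques (SD, n = 4), 35.8% ± 29.5 (n = 2) in chief adenomas and 25.8% ± 32.3 (n = 2) in oxyphil adenomas. The adenomas as a group were at 30.8% ± 25.9, a difference of -42.6 percentage points that was below every macaque gland in 4 of 4 adenomas (exact permutation test, two-sided, p = 0.0286, the smallest possible with 4 samples against 4, BH-adjusted p = 0.0952). Endothelial-like cells were 7.31% ± 4.94 of macaque and 27.0% ± 23.3 of adenoma cells (exact permutation p = 0.171, two-sided, BH-adjusted p = 0.214). T- or NK-like cells were 1.91% ± 1.32 of macaque and 15.7% ± 8.19 of adenoma cells, and myeloid-like cells 1.12% ± 1.14 and 8.71% ± 3.87. Mixed immune clusters, up to 2.17% of the cells of a macaque gland, counted toward neither class, and macaque replicate 3 had 0% T- or NK-like cells. Fibroblast-like cells were 1.20% ± 0.467 and 5.17% (range 0.987% to 9.31%), and mural-like cells 0.850% ± 0.442 and 4.81% ± 3.82. Thyroid follicular-like cells were 6.22% ± 5.15 of macaque cells and were not among the adenoma clusters, while neutrophil-like cells, 2.91% ± 0.626 of oxyphil adenoma cells, formed no cluster in the other samples. That depends on the clustering, since chief replicate 2 had a neutrophil-like cluster of 7.03% of its cells (95% Wilson interval 6.03% to 8.18%) at Leiden resolution 0.5 and of 7.61% (6.45% to 8.96%) with at least 1000 UMIs per cell. Clusters of low depth with parathyroid markers, kept apart from the parathyroid-like class, held 7.42% (range 0 to 18.2%) of macaque and 4.24% ± 8.47 of adenoma cells. Lymphatic endothelial-like, B- or plasma-like, mast-like, erythroid-like, mixed immune and unnamed clusters each held under 2% of cells in their group means. The labels record the dissociation in full for the human tissue only, so these shares may carry the protocol along with the species.

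Oxyphil adenomas carried more mitochondrial and stress-response transcript, and less ribosomal protein transcript, per parathyroid-like cell than chief adenomas. Mitochondrially encoded mRNAs, which code for core subunits of the respiratory chain, took 21.9% ± 2.58 (SD, n = 2) of the UMIs other than PTH in oxyphil and 8.33% ± 1.56 (n = 2) in chief adenomas. The gap of 13.6 percentage points exceeded the spread within either histology and was not tested as a single value. The macaque glands lay at 6.45% ± 6.25 (n = 4), with macaque replicate 1 at 15.8% and the other animals at 2.55% to 3.87%. PTH itself, the gland's hormone (ENSG00000152266, GRCh38 chromosome 11, 13492055 to 13496181), took 3.92% and 6.71% of UMIs in the oxyphil adenomas and 16.1% and 15.9% in the chief adenomas. Immediate early and heat shock transcripts were 3.36% ± 0.455 of non-PTH, non-mitochondrial UMIs in oxyphil and 0.968% ± 0.206 in chief adenomas, and ribosomal protein transcripts 12.5% ± 3.05 and 20.6% ± 3.07. In endothelial-like cells of the same libraries the mitochondrial share was 2.14% ± 0.525 in oxyphil and 2.75% ± 0.260 in chief adenomas.

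**Figure D1:**
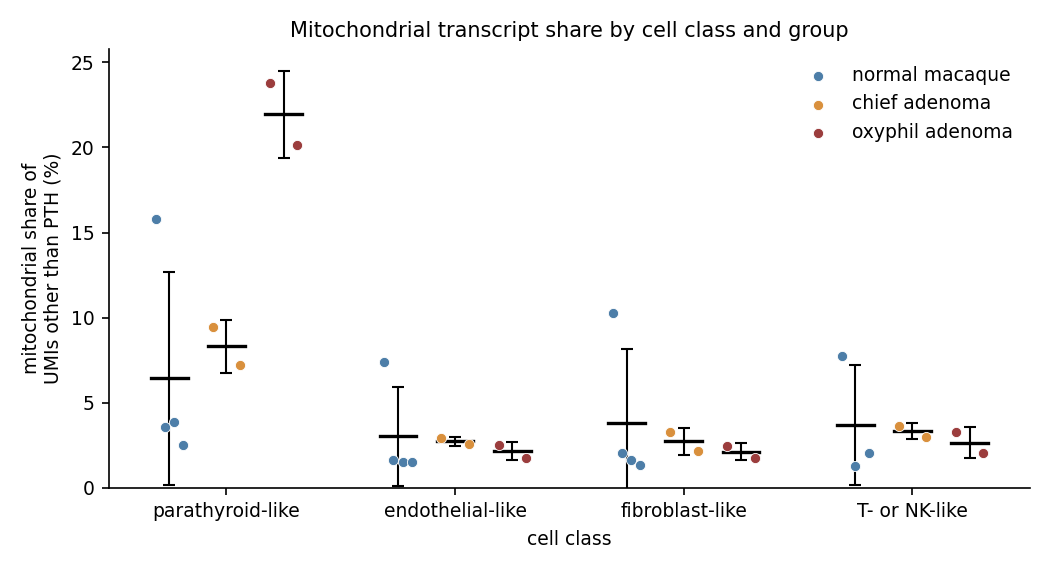
Mitochondrial transcript share (percent of UMIs other than PTH, vertical axis) by cell class and group; each point is a sample, the bar the group mean and the whisker 1 SD. In parathyroid-like cells both oxyphil adenomas lie at 20.1% and 23.8%, above both chief adenomas at 7.22% and 9.43%, while in endothelial-like cells all adenomas lie between 1.77% and 2.93%.

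With edgeR, 0 of 13155 genes passed between the histologies, with 1545 at an unadjusted p under 0.05 and 13 mitochondrial mRNAs all higher in oxyphil adenomas. DESeq2's Wald test called 394 genes, the edgeR fit without a count filter 866, and the fit of all 8 samples 962. Without chief replicate 2 the count was 10. On simulated data of this design the edgeR test found 0% of abundant genes changed 2-fold and 75.8% of those changed 16-fold. The count of 0 therefore says little about smaller changes. As groups, 5 gene lists passed with camera at the preset correlation, although no member passed alone among all genes. With fry 0 of the 22 lists passed (lowest adjusted p = 0.409). Each of the 5 lists had an adjusted p = 0.739 with an estimated correlation. The mitochondrially encoded mRNAs were higher in all 13 members, with a median log2 change of 1.61 (adjusted p = 3.0e-07; 12 higher when adjusted over the list alone). MT-ND4L, a complex I subunit, was at 2.99 ± 0.40 (SE) on the log2 scale, MT-ND5 at 1.85 ± 0.37, MT-ND4 at 2.17 ± 0.47 and MT-CO1 at 1.76 ± 0.39. The dissociation and immediate early list, genes switched on within minutes of cell stress, was higher in all 27 members with a median of 2.07 (adjusted p = 6.4e-12; 15 higher when adjusted over the list alone). Among them were HSPA1A at 4.02 ± 0.47, JUN at 3.29 ± 0.52, SOCS3 at 2.60 ± 0.49 and KLF4 at 7.18 ± 1.38 from 15 UMIs in chief adenomas. Cytosolic ribosomal protein genes were lower in 72 of 74 members, with a median of -0.82 (adjusted p = 8.3e-12; 0 when adjusted over the list alone). RPS3 was at -1.87 ± 0.41, RPS13 at -1.72 ± 0.38, RPL10 at -1.55 ± 0.35 and RPL27A at -1.71 ± 0.41. Cell cycle genes were lower in 14 of 16 members with a median of -0.84 (adjusted p = 0.0356; 0 when adjusted over the list alone). Among them were TK1 at -2.56 ± 0.96, MCM6 at -1.91 ± 0.78, MCM5 at -1.48 ± 0.76 and BIRC5 at -2.26 ± 1.18. Without chief replicate 1 the cell cycle list's adjusted p was 0.780. Metallothioneins and antioxidant genes were higher in 15 of 22 members with a median of 0.67 (adjusted p = 0.0195; 5 higher when adjusted over the list alone). Among them were the peroxidase gene GPX3 at 3.89 ± 0.66, MT2A at 4.01 ± 0.78, TXNRD1 at 2.91 ± 0.54 and GCLM at 2.65 ± 0.47. Without chief replicate 2 or oxyphil replicate 1 that adjusted p was 0.0561 and 0.260. HSPA1A, MT2A and the ribosomal protein genes have near-identical copies, so their counts are uncertain.

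The genes that mark parathyroid identity did not pass between the histologies. PTH was at -1.65 ± 0.38 (SE, log2 oxyphil over chief, adjusted p = 0.288), with 51728 CPM against 162132 after TMM scaling among the adenomas. GCM2, the transcription factor that specifies the gland (ENSG00000124827, chromosome 6, 10873223 to 10881941), was at -1.29 ± 0.54 (adjusted p = 0.437). The calcium-sensing receptor gene CASR (ENSG00000036828, chromosome 3, 122183683 to 122291629) was at -0.85 ± 0.41, the vitamin D receptor gene VDR at -1.05 ± 0.56 and the cyclin gene CCND1 at -1.45 ± 2.07. The log2 change was -0.33 ± 0.53 for GATA3, 0.27 ± 1.30 for CHGA and -0.05 ± 0.75 for RARRES2. It was 0.66 ± 0.44 for VEGFA and 1.19 ± 0.72 for PPARGC1A, a coactivator of mitochondrial biogenesis. Among lists that did not pass, the nuclear respiratory genes had medians of 0.02 for complex I (adjusted p = 0.990), 0.48 for complexes II and III (0.402), 0.52 for complex IV (0.0939) and 0.07 for complex V (0.952). The TCA cycle median was -0.05 with a mean of 0.02 and a downward test (0.990), and mitochondrial biogenesis was at 0.40 (0.990). Glycolysis and hypoxia stood at 0.06 (0.521), parathyroid identity and hormone secretion at 0.27 with a downward test (0.860), calcium, vitamin D and phosphate sensing at -0.23 (0.521), and parathyroid tumour genes at 0.21 (0.521). The unfolded protein response and ER secretion list had a median of 0.13 (0.347), angiogenic ligands 0.36 (0.990), antigen presentation 0.50 (0.383) and interferon response -0.85 (0.0939). Cholesterol and lipid synthesis stood at 0.57 (0.198), iron handling at 0.50 (0.347), and lysosome and autophagy at 0.03 (0.751). When adjusted over the list alone, 1 parathyroid tumour gene was higher, as were 3 lysosome genes with 1 lower, and no member of the other lists that did not pass. Markers of other cell types moved with the histology inside the parathyroid-like sums. The endothelial list was higher by a median of 2.02 (10 measured, adjusted p = 0.00186), T or NK by 2.93 (7 measured, 8.9e-05) and myeloid by 1.501 (10 measured, 0.0324), each with an adjusted p = 0.656 with an estimated correlation. Fibroblast markers stood at 1.55 (0.110), mural markers at 0.09 (0.794) and parathyroid markers at 0.13 (0.794).

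**Figure D2:**
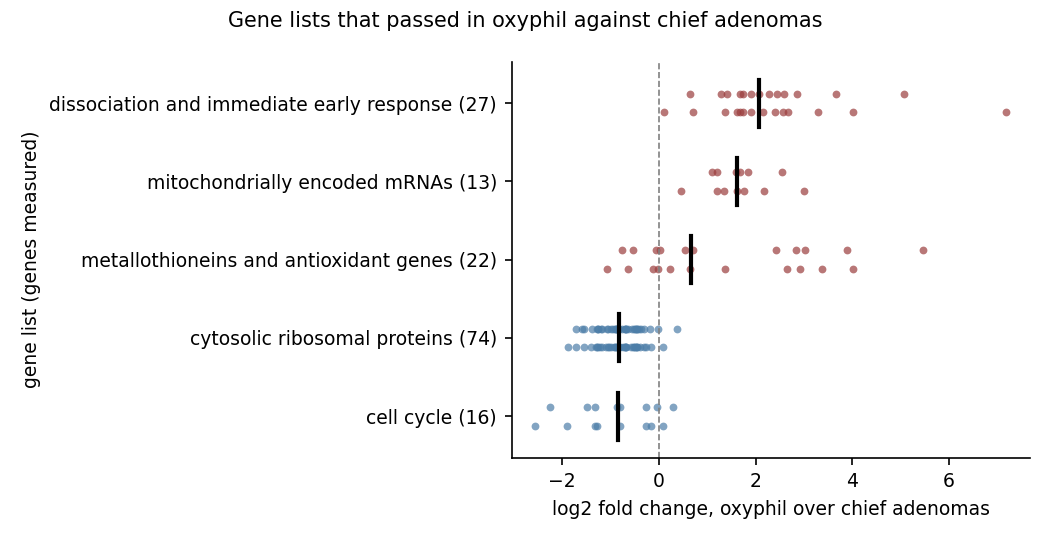
Log2 fold change of oxyphil over chief adenomas (horizontal axis) for each measured member of the gene lists that passed, with the number measured in brackets; points are genes and black bars list medians. Medians lie at 2.07 for immediate early genes and 1.61 for mitochondrial mRNAs, and at -0.82 for ribosomal proteins and -0.84 for the cell cycle.

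Adenoma cells differed from normal macaque cells in single genes, with PTH and most immediate early genes higher in the adenomas and the adipokine gene RARRES2 lower. PTH rose to a TMM-scaled 159700 ± 98587 CPM (SD, n = 4) from 14598 ± 4451 (n = 4), a log2 change of 3.45 ± 0.61 (SE, adjusted p = 0.00124). PPARGC1A rose by 1.69 ± 0.50 (adjusted p = 0.0184). RARRES2, which encodes the chemerin precursor (ENSG00000106538, chromosome 7, 150338317 to 150341674), fell by 1.68 ± 0.48 (0.0145), from a TMM-scaled 15562 ± 1980 to 4844 ± 2711 CPM. Without TMM scaling the adenoma means are lower, 106481 ± 62650 CPM for PTH and 3097 ± 1480 for RARRES2. Every adenoma was on one side of every macaque for these genes. The angiogenic factor VEGFA was lower at -0.70 ± 0.25 (0.0410) with overlapping samples. GCM2 (-0.58 ± 0.42), CASR (0.02 ± 0.29), GATA3 (-0.12 ± 0.31), CHGA (-0.50 ± 0.86), VDR (0.31 ± 0.39) and CCND1 (-1.78 ± 1.11) did not pass, with adjusted p from 0.204 to 0.953. In all, edgeR called 5855 of 10970 genes, 2965 higher and 2890 lower in adenomas, and without macaque replicate 1 and oxyphil replicate 2 it called 5201. VEGFA lost its call in 5 of the fits that left out a sample (adjusted p 0.0619 to 0.0901) and PPARGC1A in 3 (0.0509 to 0.0615), and PPARGC1A was at 1.00 without oxyphil replicate 2. Species, disease and annotation change together in this comparison and cannot be told apart. Age and dissociation may differ with them, since the labels give ages for the macaques only and the macaque protocol incompletely. The barcode sets differ between the species as well.

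There were 7 lists higher in adenomas and 0 lower, and all 7 had an adjusted p = 0.730 with an estimated correlation. The same 7 lists were also higher in the endothelial-like cells of these adenomas, with adjusted p from 3.7e-13 for ribosomal proteins to 0.0222 for mitochondrial mRNAs. That test used the preset correlation only, and PTH was seen in 77.7% of these cells after thinning. The mean mitochondrial share itself was not higher there, at 2.44% ± 0.485 in adenoma and 3.02% ± 2.93 in macaque endothelial-like cells. That macaque mean rests on macaque replicate 1 at 7.41%. The other animals, at 1.51% to 1.65%, lay below every adenoma (1.77% to 2.93%). In parathyroid-like cells the mean share was 15.1% ± 8.05 in adenomas and 6.45% ± 6.25 in macaques. Of 23 immediate early genes 22 rose and 1 did not pass (23 higher when adjusted over the list alone; median 3.46, adjusted p = 5.0e-05). Examples are JUNB at 7.94 ± 0.86, JUND at 6.18 ± 0.65, NR4A1 at 5.57 ± 0.86 and DNAJB1 at 5.00 ± 0.84. Of 13 mitochondrial mRNAs 5 rose and 8 did not pass (5 over the list alone; median 2.66, adjusted p = 0.00250). Examples are MT-ND1 at 10.39 ± 0.97, MT-CYB at 9.81, MT-ND5 at 5.89 ± 0.86 and MT-ND3 at 3.70 ± 0.62. MT-ND1, MT-ND5 and MT-CYB together held 0.168% of the mitochondrial UMIs in macaque endothelial-like cells and 17.3% in those of adenomas, so part of this list differs in every cell type examined. Complex IV subunits rose in 10 of 12 (10 over the list alone; median 1.53, adjusted p = 0.00244). Among them were COX7A2 at 2.06 ± 0.32, COX17 at 2.19 ± 0.34, COX7C at 1.67 ± 0.28 and COX7A2L at 11.59 ± 0.43 from 21 macaque UMIs. Complex V rose in 9 of 15 (9 over the list alone; median 0.92, adjusted p = 0.0123). Among them were ATP5F1B at 3.67 ± 0.34, ATP5PB at 1.37 ± 0.34, ATP5F1C at 1.21 ± 0.31 and ATP5PF at 0.94 ± 0.25. Of 31 complex I genes 12 rose, 1 fell and 18 did not pass (12 and 1 over the list alone; median 0.52, adjusted p = 0.0123, and 0.0537 without chief replicate 1). Among them were NDUFB3 at 3.15 ± 0.24, NDUFB1 at 2.07 ± 0.28, NDUFB4 at 1.81 ± 0.29 and NDUFB8 at 1.61 ± 0.24. Ribosomal protein genes rose in 26 of 59 and fell in 1 (24 and 1 over the list alone; median 0.58, adjusted p = 0.00244). Examples are RPL31 at 4.58 ± 0.39, RPL32 at 3.47 ± 0.38, RPL26 at 3.14 ± 0.36 and RPL17 at -2.60 ± 0.25. Of 18 metallothionein and antioxidant genes 10 rose and 8 did not pass (10 higher and 1 lower over the list alone; median 1.37, adjusted p = 0.0127). Among them were GPX4 at 2.01 ± 0.21, NQO1 at 3.82 ± 0.41, GPX3 at 6.22 ± 1.19 and MT1F at 2241 times the macaque level (95% counting interval 620.3 to 18504, from 2 macaque UMIs). The other 15 lists had adjusted p from 0.0515 (complexes II and III, 6 higher and 1 lower of 11, median 1.32) to 0.863. Among them the median, mean and test differed in sign for the TCA cycle (0.10, -0.03 and down), calcium sensing (-0.19, 0.31 and down), tumour genes (-0.49, 0.21 and down) and the cell cycle (-0.11, 0.10 and down). Fry, which asks only whether a list moves one way, passed 11 lists. Marker lists of other cell types had adjusted p from 0.0720 for myeloid (median 3.95) to 0.943 for fibroblast (2.65, test downward), with thyroid follicular at -6.98 (3 measured, 0.153), endothelial at 1.88 (0.153), mural at 1.37 (0.442), T or NK at 1.75 (0.730) and parathyroid at 1.22 (0.144). TG, the thyroglobulin gene, gave 4653 UMIs in macaque parathyroid-like cells (45.9 ± 34.9 CPM) and 0 in adenomas.

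Among genes with an average log2 CPM of at least 5 over both species, the widest single-gene gaps were at or near zero counts in 1 species. There a lack of counting cannot be separated from a lack of expression. INSC, an adaptor of cell polarity, was at least 12818-fold higher in adenomas (14251 UMIs against 0 over the macaques) and the immediate early factor EGR3 at least 5562-fold higher. The ratio was 13909 for MALL (2496 to 549392), 4319 for HSD17B8 (1195 to 35659) and 4304 for DKK3 (772.4 to 169986), each from 1 or 2 macaque UMIs. TTR and PTN were at 11.88 ± 1.74 and 11.83 ± 1.79 on the log2 scale. In the other direction, AHRR was at least 2255-fold, PIGY at least 2163-fold, PRSS55 at least 1065-fold and the receptor kinase gene ROS1 at least 1019-fold lower in adenomas, against 0 human UMIs. The macaque to human ratio was 13218 for TNMD (4523 to 64093), 9263 for BCL2L2-PABPN1 (1663 to 365887) and 7338 for GSTM5 (1317 to 289841), and GLB1L3 was at -9.88 ± 0.84. PIGY, BCL2L2-PABPN1, GSTM5 and MT1F overlap other genes or have close paralogs. The endothelial-like cells of the same samples, compared the same way, shared 2325 of 3630 parathyroid calls with the same sign (64.0%), where independent lists would share 913, and 112 calls had the opposite sign. The fold changes correlated across genes with a Pearson r of 0.744 and a Spearman rho of 0.698. Genes are not independent replicates, and both comparisons use the same animals and donors.

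Within normal macaque glands, PTH-high cells had more mitochondrial transcript and less ribosomal protein and immediate early transcript than PTH-low cells. The ranking sets PTH against UMIs that are neither PTH nor mitochondrial, so cells low in such RNA rank high in PTH and mitochondrial share alike. With PTH over all UMIs, the macaque log2 ratio of the mitochondrial share was 0.258, above 0 in 3 of 4 animals, against 0.370. With an estimated correlation the lists below had an adjusted p = 0.677, and complex I an adjusted p = 0.715. All 13 mitochondrially encoded mRNAs rose from PTH-low to PTH-high cells (13 when adjusted over the list alone), with a median log2 change of 0.41 (adjusted p = 8.2e-05). Among them MT-ND6 rose by 0.69 ± 0.12 (SE, 4 pairs), MT-ND5 by 0.47 ± 0.10, MT-ND3 by 0.43 ± 0.11 and MT-ND4 by 0.40 ± 0.10. Ribosomal protein genes fell in 50 of 59 (55 over the list alone; median -0.40, adjusted p = 6.7e-23). RPL7A was at -0.66 ± 0.09, RPS2 at -0.59 ± 0.09 and RPS13 at -0.53 ± 0.08. Immediate early genes fell in 14 of 21 (16 lower and 1 higher over the list alone; median -0.97, adjusted p = 7.9e-07). They include FOS at -1.40 ± 0.21, ATF3 at -1.33 ± 0.23, ZFP36 at -1.22 ± 0.21, DUSP1 at -1.11 ± 0.14, JUN at -1.10 ± 0.17, GADD45B at -1.01 ± 0.22, EGR1 at -0.99 ± 0.17, NR4A1 at -0.98 ± 0.14 and FOSB at -0.97 ± 0.15. Lysosome and autophagy genes fell in 6 of 22 (8 over the list alone; median -0.13, adjusted p = 0.00906). They include GABARAP at -0.58 ± 0.09, BNIP3L at -0.39 ± 0.07, SQSTM1 at -0.30 ± 0.06 and ATP6V0D1 at -0.28 ± 0.06. Nuclear complex I genes fell in 7 of 31 (7 over the list alone; median -0.08, adjusted p = 0.0245). They include NDUFS6 and NDUFB9 both at -0.33 ± 0.07, NDUFA8 at -0.26 ± 0.06 and NDUFAB1 at -0.25 ± 0.06. Without macaque replicate 2 or 3 this list's adjusted p was 0.143 and 0.0933. Without macaque replicate 2, MT-ND5 was at 0.30, MT-ND3 at 0.24, ATF3 at -0.79, ZFP36 at -0.80, EGR1 at -0.63, GADD45B at -0.62 and FOSB at -0.64.

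Among genes with an average log2 CPM of at least 5 that moved the same way in 4 of 4 animals, the largest rises in PTH-high macaque cells were in LAMA4, a laminin chain of the vascular basement membrane, at 0.97 ± 0.08, ZMAT1 at 0.78 ± 0.18, the lysosomal sialic acid transporter gene SLC17A5 at 0.76 ± 0.09 and E-cadherin's gene CDH1 at 0.73 ± 0.09. TTC14 at 0.73 ± 0.13, the protease gene PAPPA at 0.71 ± 0.12 and FAR1 at 0.68 ± 0.09 followed. The largest fall of such genes was in CGA, which encodes the alpha subunit shared by pituitary glycoprotein hormones, at -1.71 ± 0.29. Of the fixed genes, GCM2 rose by 0.40 ± 0.09 (adjusted p = 0.01001) and VEGFA by 0.35 ± 0.09 (0.0190), and VDR fell by 0.37 ± 0.07 (0.00392), each in 4 of 4 animals. Without macaque replicate 2, VEGFA was at 0.19 (adjusted p = 0.0678), GCM2 at 0.24, ZMAT1 at 0.37 and TTC14 at 0.48, and without macaque replicate 4 CGA was at -2.76. CASR (0.08 ± 0.07), GATA3 (-0.02 ± 0.07), CHGA (0.29 ± 0.11), CCND1 (0.15 ± 0.07), RARRES2 (-0.07 ± 0.10) and PPARGC1A (0.06 ± 0.08) did not pass, with adjusted p from 0.0699 to 0.906. In total 2193 of 12024 genes passed, 1010 higher and 1183 lower. Without macaque replicate 1, whose parathyroid-like cells have a mitochondrial share of 15.8% against 2.55% to 3.87% in the other animals, 835 passed, and GCM2 (adjusted p = 0.0503), VEGFA (0.127), ZMAT1 (0.0606), MT-ND3 (0.105) and MT-ND4 (0.0812) were among 8 named genes that did not. The log2 changes of these 5 genes stayed near those of all animals, at 0.43, 0.29, 0.73, 0.41 and 0.34. DESeq2's Wald test called 967 genes, 314 higher and 653 lower. The other 17 lists had adjusted p from 0.0757 to 0.972, and the median, mean and test differed in sign for complexes II and III (-0.04, 0.05 and down), calcium sensing (0.05, 0.02 and down) and ER secretion (-0.02, 0.04 and up). With fry only 1 list passed, angiogenic ligands at a median of 0.20 (adjusted p = 0.00773), and none of the lists that camera called. Marker lists of parathyroid (median 0.19), endothelial (-0.01), mural (0.08), fibroblast (-0.06) and myeloid cells (-0.18) had adjusted p from 0.479 to 0.923.

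Within the adenomas, PTH-high cells carried more transcript of the nuclear-encoded respiratory chain and TCA cycle, and no change of the mitochondrially encoded mRNAs was found. With an estimated correlation the rising lists had an adjusted p = 0.635 and the immediate early list an adjusted p = 0.878. Most respiratory and TCA genes named below as rising lost their calls without chief replicate 1, chief replicate 2 or oxyphil replicate 1 alike. Of the exceptions, NDUFB6 lost its call without chief replicate 2, and NDUFS3, DLD and SUCLG1 lost theirs without chief replicate 2 and also without oxyphil replicate 1. The respiratory and TCA lists kept their calls at the preset correlation with any 1 adenoma left out. Nuclear complex I genes rose in 15 of 38 (31 when adjusted over the list alone; median log2 change 0.36, adjusted p = 3.7e-12). These include NDUFB6 at 0.61 ± 0.12 (SE, 4 pairs), NDUFS3 at 0.57 ± 0.12, NDUFB4 at 0.49 ± 0.12 and NDUFA5 at 0.48 ± 0.12. Complex V genes rose in 8 of 18 (17 over the list alone; median 0.38, adjusted p = 5.9e-08). These include ATP5F1C and ATP5MC3 at 0.50 ± 0.12, ATP5MF at 0.47 ± 0.11 and ATP5F1B at 0.45 ± 0.11. TCA cycle genes rose in 9 of 17 (11 over the list alone; median 0.45, adjusted p = 1.6e-06). Among them were DLD at 0.55 ± 0.13, SUCLA2 at 0.53 ± 0.12, SUCLG1 at 0.52 ± 0.12 and PDHB at 0.49 ± 0.12. Complexes II and III rose in 3 of 14 (7 over the list alone; median 0.31, adjusted p = 4.7e-05), SDHD at 0.53 ± 0.12, SDHB at 0.47 ± 0.12 and SDHC at 0.40 ± 0.12, while CYCS was at 0.38 ± 0.12 (adjusted p = 0.0551). Complex IV rose in 3 of 14 (6 over the list alone; median 0.28, adjusted p = 4.7e-05), COX6C at 0.52 ± 0.12, COX7B at 0.51 ± 0.12 and COX6A1 at 0.41 ± 0.12. Lysosome genes rose in 3 of 21 (4 over the list alone; median 0.19, adjusted p = 0.00636), LAMP2 at 0.69 ± 0.13, CTSA at 0.54 ± 0.13 and NPC2 at 0.39 ± 0.12. Antioxidant genes rose in 2 of 20 (3 over the list alone; median 0.21, adjusted p = 0.0361), the peroxiredoxins PRDX2 at 0.58 ± 0.11 and PRDX3 at 0.42 ± 0.12. Immediate early genes fell in 9 and rose in 2 of 27 (16 lower and 4 higher over the list alone; median -0.43, adjusted p = 0.0361). Examples are NR4A2 at -1.15 ± 0.18, EGR2 at -1.04 ± 0.20, FOSB at -0.91 ± 0.16 and JUND at -0.82 ± 0.12. The mitochondrially encoded mRNAs had a median of 0.03 with 0 of 13 passing (adjusted p = 0.953), and the ribosomal proteins a median of 0.03 with 0 of 74 (0.657).

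Among adenoma genes with an average log2 CPM of at least 5 that moved the same way in 4 of 4 tumours, the largest rises were in INSC at 1.09 ± 0.19, the secreted protein gene C1QTNF4 at 1.03 ± 0.17, the heat shock gene HSPA6 at 0.96 ± 0.18, the proton pump subunit gene ATP6AP2 at 0.81 ± 0.12, the tetraspanin gene CD9 at 0.80 ± 0.12, TECR at 0.75 ± 0.14 and the malate dehydrogenase gene MDH1 at 0.70 ± 0.12. The largest falls were in RGCC at -1.85 ± 0.23, NEDD9 and the elongation factor gene ELL2 at -0.99 ± 0.18, SPSB1 at -0.97 ± 0.17, FABP5 at -0.93 ± 0.19, the histone demethylase gene KDM6B at -0.91 ± 0.14 and YBX3 at -0.86 ± 0.15. Without oxyphil replicate 2, HSPA6 was at 0.61 and FABP5 at -0.47 (adjusted p = 0.0699), and without oxyphil replicate 1 FABP5 was at -1.46 and ELL2 at -0.65 (0.206). INSC was at 0.68 without chief replicate 1 (0.0584), and ELL2 (0.0599) and FABP5 (0.123) lost their calls without chief replicate 2. The secretory granule gene CHGA rose by 0.79 ± 0.22 (adjusted p = 0.0339, 3 of 4 adenomas) and RARRES2 by 0.39 ± 0.12 (0.0489, 4 of 4). CHGA was at 0.29 without oxyphil replicate 2 (adjusted p = 0.212) and lost its call without chief replicate 2 (0.213), and RARRES2 lost its call without any of the other 3 adenomas (0.137 to 0.241). GCM2 (0.21 ± 0.13), CASR (-0.18 ± 0.12), GATA3 (-0.21 ± 0.12), VDR (0.00 ± 0.12), CCND1 (-0.38 ± 0.26), PPARGC1A (-0.28 ± 0.14) and VEGFA (-0.37 ± 0.14) did not pass, with adjusted p from 0.111 to 0.993. In all 452 of 10194 genes passed, 277 higher and 175 lower, against 210 with DESeq2's Wald test (179 higher and 31 lower). The balance of directions is not stable, with 67 higher and 135 lower (202) without chief replicate 1, 9 and 32 (41) without chief replicate 2, and 33 and 36 (69) without oxyphil replicate 1. Of 43 named calls, 19 and 31 were lost in the first 2 of these fits and 24 of the 41 tested in the last, while 2 were lost without oxyphil replicate 2. At a mitochondrial limit of 20% the balance was 10 higher and 24 lower. The PTH-low cells of chief replicate 2 had a median of 977 UMIs against 11546 in its PTH-high cells, and 30 cells per group stand for oxyphil replicate 2. The immediate early, antioxidant and lysosome lists lost their calls without chief replicate 2 (adjusted p = 0.513, 0.0830 and 0.0951), the first 2 also without chief replicate 1 (0.264 and 0.123) or oxyphil replicate 1 (0.237 and 0.306). The other 14 lists had adjusted p from 0.0903 to 0.953, and mitochondrial biogenesis had a median of -0.03 with an upward test. With fry only 1 of the 22 lists passed. Marker lists had medians of -0.18 for parathyroid (0.364), -0.38 for endothelial (0.0944) and -0.13 for myeloid (0.579).

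The change over the PTH range was tested for a difference between adenomas and macaques. Of 10841 genes, 1518 differed, 900 with a higher and 618 with a lower change in adenomas. Without oxyphil replicate 1 the count was 843. The lists that passed had an adjusted p = 0.337 with an estimated correlation, except mitochondrial mRNAs (0.484), complex IV (0.431) and immediate early genes (0.789). With fry 8 of the 22 lists passed. The mitochondrially encoded mRNAs changed less in adenomas (1 of 13 lower, 6 when adjusted over the list alone; median -0.39, adjusted p = 0.000724), as did MT-ND6 at -0.73 ± 0.17 (SE), with overlapping samples, which lost its call without oxyphil replicate 1 (-0.53, adjusted p = 0.0992). The nuclear lists went the other way. Complex I was higher in 23 of 31 (28 over the list alone; median 0.43, adjusted p = 2.7e-12), such as NDUFV1 at 0.69 ± 0.12 and NDUFS3 at 0.69 ± 0.13, and complexes II and III in 6 of 11 (9 higher and 1 lower over the list alone; 0.41, adjusted p = 0.000993), such as SDHA at 0.52 ± 0.12. Complex IV was higher in 4 of 12 (6 over the list alone; 0.33, adjusted p = 0.000350), complex V in 8 of 15 (12; 0.44, 1.0e-07) and the TCA cycle in 10 of 17 (10; 0.48, 7.5e-07), with COX5A at 0.65 ± 0.15, ATP5MC1 at 0.79 ± 0.14 and SUCLG1 at 0.77 ± 0.13. Glycolysis and hypoxia was higher in 6 of 22 (8 higher and 1 lower; 0.29, 0.0207), with PGK1 at 0.67 ± 0.13 and ALDOA at 0.72 ± 0.15, and its adjusted p was 0.0944 without chief replicate 1. Ribosomal proteins were higher in 30 of 59 (43; 0.42, 2.8e-18), with RPSA at 0.71 ± 0.15, antioxidant genes in 7 of 19 (8 higher and 2 lower; 0.30, 0.00535), with PRDX2 at 0.65 ± 0.13, and lysosome genes in 6 of 22 (6; 0.23, 4.8e-05), with LAMP2 at 0.72 ± 0.13. Immediate early genes were higher in 3 and lower in 2 of 24 (5 and 3; 0.40, 0.0299), FOS at 1.19 ± 0.26 and JUND at -0.70 ± 0.17, and that call was lost without macaque replicate 1, macaque replicate 2 or oxyphil replicate 2 (adjusted p = 0.0675, 0.212 and 0.621). The other 11 lists had adjusted p from 0.199 to 0.880. Lists whose median, mean and test differed in sign included mitochondrial biogenesis (0.06, -0.04, up), antigen presentation (0.02, 0.02, down), interferon response (0.09, -0.03, down) and cholesterol synthesis (-0.06, -0.09, up). Marker lists had adjusted p from 0.441 to 0.899, with Schwann or neural markers at -0.54 (3 measured, 0.623). Lymphatic endothelial, B or plasma, neutrophil, mast, C cell, thymic epithelial, thymocyte, adipocyte and erythroid lists had too few measured members to be tested in any comparison.

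Genes that passed over both ranges overlapped more across directions than along them. Of the 8247 genes tested in both, 5 rose in both where 19.4 were due by chance (Fisher's exact test, two-sided, p = 9.9e-05), and 16 fell in both against 16.2 (p = 1). By the same exact test, 52 fell in macaques and rose in adenomas against 27.2 by chance (p = 3.6e-06). Another 21 rose in macaques and fell in adenomas against 11.5 (exact p = 0.00742). The fold changes correlated across genes at a Pearson r of -0.182 and a Spearman rho of -0.228. Genes are not independent replicates, so neither these values nor the exact p-values measure variation between animals or adenomas. The adenoma calls that enter the overlap were also unstable when a tumour was left out.

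**Figure D3:**
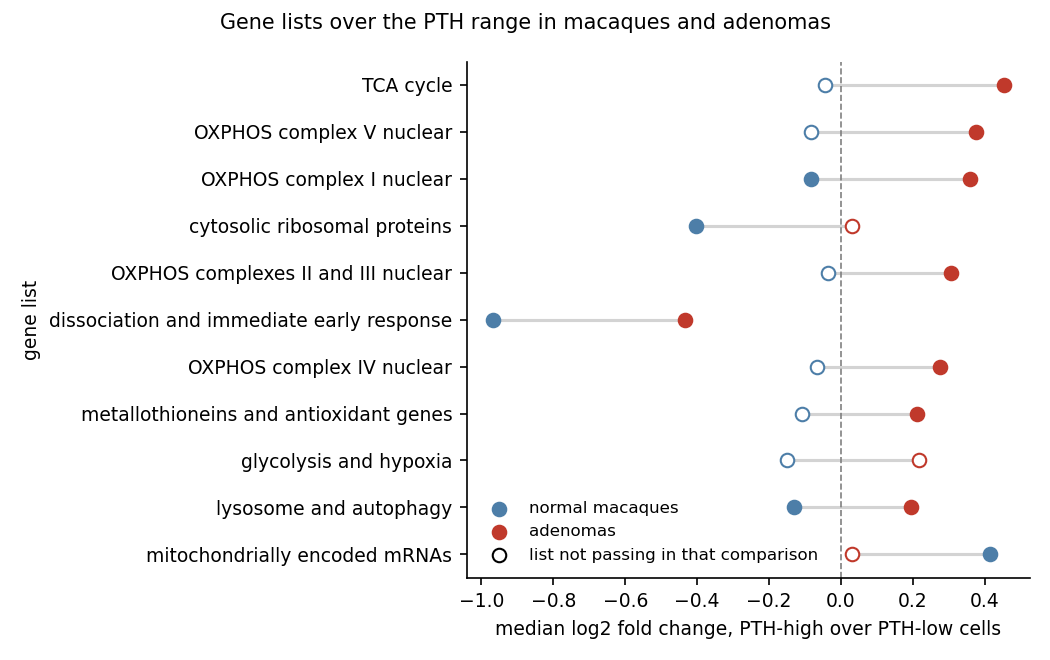
Median log2 fold change of PTH-high over PTH-low cells (horizontal axis) for the gene lists whose change differed between species; each point is a list in macaques or adenomas, filled where the list passed in that comparison. Mitochondrial mRNAs lie at 0.41 in macaques and 0.03 in adenomas, and complex I at -0.08 and 0.36.

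The mitochondrial transcript share followed the same pattern when taken as a single value per sample. The log2 ratio of PTH-high over PTH-low cells was 0.370 ± 0.337 (SD, n = 4) in macaques, above 0 in 4 of 4 (exact sign-flip permutation test, two-sided, p = 0.125, the smallest possible). In adenomas it was -0.114 ± 0.231, above 0 in 1 of 4 (exact p = 0.625), and over all 8 samples 0.128 ± 0.372, above 0 in 5 (exact p = 0.305, BH-adjusted p = 0.339). For the mitochondrial transcript share PTH-high vs PTH-low, macaques were at 0.224 without macaque replicate 2, which alone was at 0.808. For the mitochondrial transcript share PTH-high vs PTH-low, adenomas were at 0.000261 without oxyphil replicate 2, which alone was at -0.455. Over all 8 the ratio was 0.0310 without macaque replicate 2, 0.0807 without macaque replicate 1 and 0.211 without oxyphil replicate 2. The difference between adenomas and macaques was -0.483 (exact permutation p = 0.0286, the smallest possible, BH-adjusted p = 0.0952). Taken as the median of per-cell shares the difference was 0.322 in the other direction (exact p = 1), where the PTH-low cells of chief replicate 2 had a median share of 0.389%. With cells ranked within bins of depth the macaque ratio was 0.230. With PTH taken over all UMIs it was 0.258, above 0 in 3 of 4 animals, and -0.344 in adenomas, above 0 in 0 of 4. Between adenomas and macaques, the mitochondrial share of all parathyroid-like cells differed by 8.69 percentage points (exact permutation p = 0.171, two-sided, BH-adjusted p = 0.214).

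**Figure D4:**
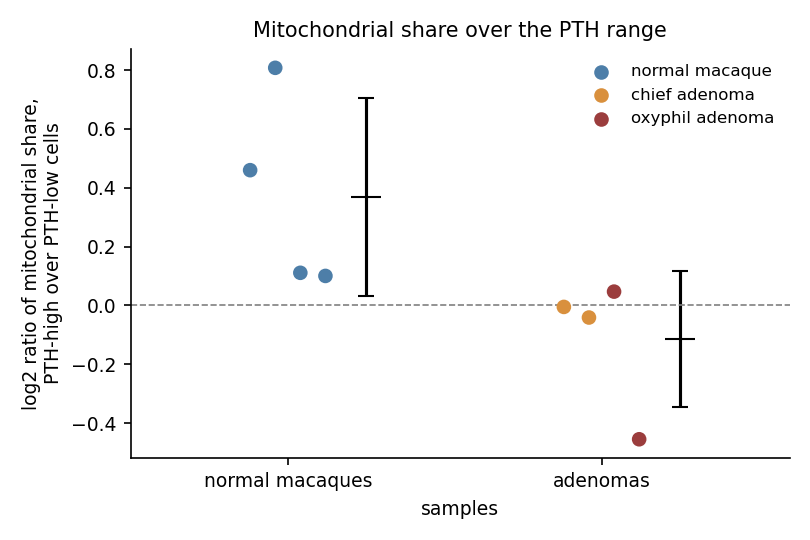
Log2 ratio of the mitochondrial transcript share in PTH-high over PTH-low cells (vertical axis), with a point per sample coloured by group, and the mean and 1 SD beside them. All 4 macaques lie above 0, and 1 of the 4 adenomas does.

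RARRES2 transcript was higher in parathyroid-like than in endothelial-like cells. Its level was 15883 ± 2335 CPM without TMM scaling (SD, n = 4) in macaque and 3097 ± 1480 in adenoma parathyroid-like cells, against 1500 ± 494 and 160 ± 224 in endothelial-like cells. The log2 difference between the classes was 4.33 ± 1.31 over the 8 samples and above 0 in 8 of 8 (exact sign-flip permutation test, two-sided, p = 0.00781, the smallest possible, BH-adjusted p = 0.0781), with 3.46 ± 0.380 in macaques and 5.21 ± 1.35 in adenomas (exact p = 0.125 each). With doublets kept, the macaque difference was 1.80. After thinning to 1000 UMIs, RARRES2 was seen in 99.5% of macaque parathyroid-like cells and 49.7% of macaque endothelial-like cells, and in 86.0% and 11.9% of those of adenomas. Other stromal classes lay above the endothelial-like cells, with 71.7% of macaque and 40.1% of adenoma fibroblast-like cells and 59.4% and 15.9% of mural-like cells. PTH, which endothelial cells should lack, was seen in 28.1% and 77.7% of the endothelial-like cells in the same way. Fibroblast-like cells had PTH in 38.7% of macaque and 68.6% of adenoma cells, and mural-like cells in 54.1% and 71.6%. Median depths were 3085 to 11830 UMIs in parathyroid-like and 790.5 to 2207.5 in endothelial-like cells. Of the chemerin receptor genes, CMKLR1 was at 5.45 ± 2.37 CPM in macaque and 12.6 ± 6.49 in adenoma endothelial-like cells (26 and 106 UMIs), with 3 and 1 UMIs over the parathyroid-like cells. CCRL2 was at 12.5 ± 6.65 CPM in macaque (n = 3) and 92.4 ± 61.2 in adenoma myeloid-like cells. GPR1 had 0 UMIs in macaque parathyroid-like cells and 3 in those of adenomas. VEGFA was at 116 ± 25.3 and 48.4 ± 21.2 CPM in macaque and adenoma parathyroid-like cells and at 44.6 ± 5.53 (n = 3) and 61.6 ± 13.5 in myeloid-like cells. The genes of its receptors, KDR at 1065 ± 198 and 316 ± 130 CPM and FLT1 at 1265 ± 424 and 730.1 ± 281, were in endothelial-like cells. Both are among the markers that named this class, so their presence there is partly built in. In myeloid-like cells PTH was at 21.1% to 33.6% of the parathyroid-like level in macaques and 0.570% to 6.87% in adenomas. The VEGFA level of the macaque myeloid-like cells may therefore include background RNA.

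**Figure D5:**
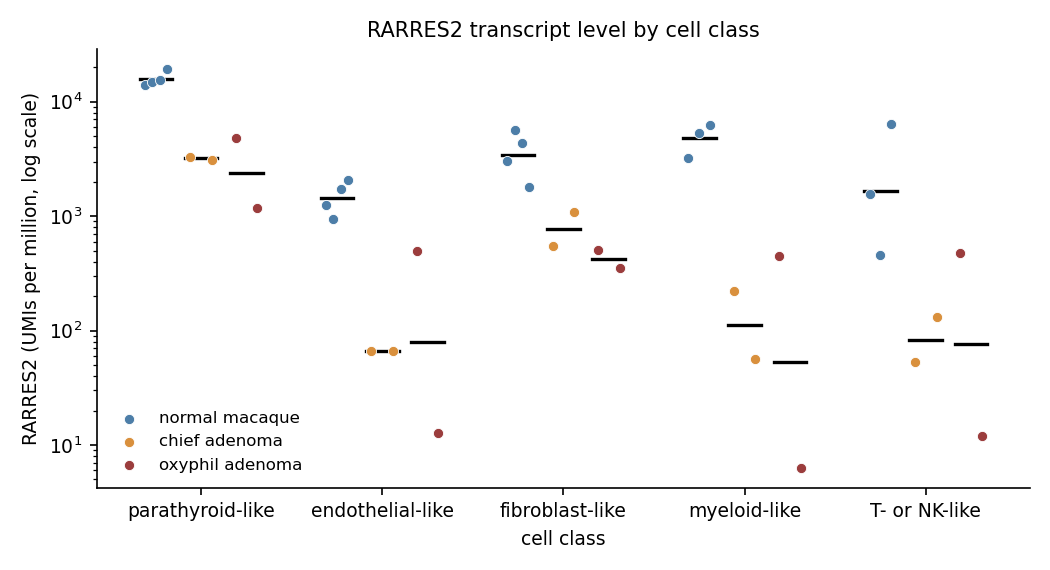
RARRES2 level (CPM, log axis) by cell class; each point is a sample coloured by group and the bar is the group's geometric mean. Parathyroid-like cells lie highest in every sample, with endothelial-like cells at 6.30% to 11.3% of that level in macaques and 1.09% to 10.3% in adenomas.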

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

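The depth-bin, RARRES2 and ER secretion tests of the macaque mitochondrial pattern, and the endothelial-like ratio of the oxyphil pattern, were chosen only after those patterns were seen. Among 25 measures of the 4 macaques, 3 had a sample far from the others by Dixon's test at its 95% critical value, where chance alone marks about 1 in 20. Macaque replicate 1 had a median mitochondrial share of 13.8% per kept cell against 1.94% to 3.35% in the other animals, and 15.8% in its parathyroid-like cells against 2.55% to 3.87%. Its endothelial-like share of mitochondrial UMIs was high too, at 7.41%. Macaque replicate 4 had 14.7% endothelial-like cells against 4.57% to 5.01%.

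The change over the PTH range differed between adenomas and macaques in 1518 genes, by the interaction test. The genes below are those with the widest difference among genes with an average log2 CPM of at least 5 whose samples did not overlap. That average is over both species, so a gene can pass with few counts in 1 of them. PTN is such a case, named above among gaps at or near zero counts in 1 species. The change was higher in adenomas for CGA by a log2 of 7.40 ± 1.05 (SE), PTN by 2.08 ± 0.56, CD9 by 1.06 ± 0.14, C1QTNF4 by 1.05 ± 0.17, PDRG1 by 1.05 ± 0.13, EMP2 by 1.02 ± 0.16, RPA2 by 0.94 ± 0.18 and ACADS by 0.94 ± 0.23. It was lower for LAMA4 at -2.67 ± 0.81, PDZRN4 at -1.69 ± 0.57, the histone methyltransferase gene SETD2 at -1.50 ± 0.22, ARHGDIB at -1.28 ± 0.36, ENAH at -1.17 ± 0.15, GPATCH2 at -1.11 ± 0.18, TIMP3 at -1.08 ± 0.17 and JMY at -1.04 ± 0.20. Of the fixed genes, VEGFA differed by -0.73 ± 0.17 (adjusted p = 0.00328, with overlapping samples) and RARRES2 by 0.45 ± 0.16 (0.0476). RARRES2 lost its call without any 1 of the 8 samples. Without chief replicate 1, CGA was at a log2 of 6.47 with an adjusted p of 0.444. PTN was at 1.09 without macaque replicate 1 (adjusted p = 0.684), and ARHGDIB at -2.56 without oxyphil replicate 1. LAMA4 turned to 0.26 with at least 1000 UMIs per cell, where it did not pass, and lost its call without chief replicate 2 (0.173) or oxyphil replicate 1 (0.0551), and ACADS (0.0568) and ARHGDIB (0.159) without chief replicate 2. PDZRN4 lost its call without macaque replicate 1 or 2, either chief adenoma or oxyphil replicate 1 (adjusted p up to 0.180).

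Among gene lists, the median difference between species was -0.39 for mitochondrially encoded mRNAs. It was 0.43 for complex I, 0.41 for complexes II and III, 0.33 for complex IV, 0.44 for complex V and 0.48 for the TCA cycle. Glycolysis and hypoxia stood at 0.29, immediate early genes at 0.40, ribosomal proteins at 0.42, antioxidant genes at 0.30 and lysosome genes at 0.23. The mitochondrial share's log2 ratio differed by -0.483 (exact permutation test, two-sided, p = 0.0286, the smallest possible, BH-adjusted p = 0.0952).

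Why PTH-high macaque cells carry more mitochondrial transcript was weighed against 3 technical causes. Depth may account for part of it, since within 5 bins of depth the mean log2 ratio was 0.230 in place of 0.370, with macaque replicate 2 at 0.309 in place of 0.808. It does not account for all, as 4 of 4 animals stayed above 0. For free RNA from lysed cells, RARRES2 was examined, and it was at -0.0654 ± 0.0950 (SE) where PTH, which ranks the cells, differed by at least 1.11. This cannot decide the question. Most macaque cells are parathyroid-like, so free RNA may hold PTH and RARRES2 in the proportion of these cells and leave their RARRES2 share unchanged. Cells that lost cytosolic RNA might keep PTH and ER transcripts; the ER secretion list had a median of -0.0153 with members both ways, which leaves this undecided. The ranking could also tie PTH and mitochondrial share together, since its denominator leaves out mitochondrial UMIs and cells low in other RNA rank high for both. With PTH over all UMIs, a denominator that includes the mitochondrial ones, the ratio was 0.258, above 0 in 3 of 4 animals. How much the ranking adds was not separated. Immediate early transcript, lower in PTH-high cells (list median -0.97), also went with the share. In 4 of 4 animals the mitochondrial share was higher in cells with the lowest than with the highest immediate early share. In macaque replicates 1 to 4 it was 18.28% against 14.03%, 5.37% against 2.71%, 4.82% against 3.32% and 3.57% against 2.05%. Whether the PTH range adds to this association was not tested. No biological explanation was tested.

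The higher mitochondrial share of oxyphil adenomas was weighed against a difference of whole libraries, which could come from the software version or from dissociation. The oxyphil to chief ratio was 0.780 in endothelial-like cells of the same libraries and 2.64 in parathyroid-like cells, so a cause acting on all cells alike is unlikely. A larger immediate early response could also raise the share. In the cells with the lowest immediate early share, the lower oxyphil adenoma still had 20.7% mitochondrial transcript, against at most 10.6% in any such range of the chief adenomas. The biological alternative is the histology itself, since oxyphil cells are known for their many mitochondria, but the share itself was not tested, and the mitochondrial mRNA list had an adjusted p of 3.0e-07, or 0.739 with an estimated correlation.

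Whether the wide gap between adenomas and macaques belongs to parathyroid cells was asked of the endothelial-like cells. Of the parathyroid calls tested in both, 64.0% were called there with the same sign, which suggests species, annotation or library differences common to cell types, although part of the excess may come from the shared libraries. MT-ND1, MT-ND5 and MT-CYB held 0.168% of the mitochondrial UMIs of macaque endothelial-like cells (at most 0.307%) and 17.3% of those of adenomas (at least 15.7%), in line with a counting difference for these genes. Disease was not separated from species by any test.

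Other splits of the same samples were fitted in the same way. Of 35 splits, only 1, the real one, called as many genes for adenomas against macaques (5855, and at most 0 in any other) and 1 for the interaction (1518, at most 11). Every other split puts macaques and adenomas into both arms, where the species difference counts as spread within an arm. The low counts therefore do not show how many calls chance alone would give. Of 8 splits of the pairs, 1 called as many over the macaque range (2193, at most 0 in the others) and 1 over the adenoma range (452, at most 38), too few splits for a p under 0.05. Over all 32 splits that could be fitted, the highest other counts were 1486 and 40. These are not chance counts, since both come from splits that part only 2 pairs and keep the real contrast in them. For the 1486 those pairs were macaque replicates 1 and 2, so much of the macaque result rests on these animals.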

How the results depend on the processing

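Ranks within depth bins, leaving out shallow clusters, adding low-depth clusters with parathyroid markers, asking at least 3 UMIs in every sample, and leaving out macaque replicate 1 with oxyphil replicate 2 were chosen only after the data were seen. Of single-gene values, 1274 kept their side of the threshold and 20 lost the call for adenomas against macaques, 712 and 54 over the macaque range, 786 and 195 over the adenoma range, and 1359 and 74, with 1 reversed, for the interaction. No gene had a call to lose between the histologies, where 38 values gained one. Gained calls numbered 3 for adenomas against macaques, 4 over the macaque range, 14 over the adenoma range and 32 for the interaction. Of list values 615 stayed on their side and 58 lost the call. Where a result below changed, the cause was not tested unless given. The mitochondrial gap between oxyphil and chief adenomas was 7.16 points at a limit of 20%, which removes most oxyphil cells, and 11.8 to 15.4 with a sample left out. The mitochondrial transcript share PTH-high vs PTH-low, adenoma minus macaque, was -0.359 at that limit (exact p = 0.114) and 0.322, reversed, as a median of per-cell shares (exact p = 1), with -0.573 to -0.337 when a sample was left out (exact p up to 0.114). The difference in parathyroid-like share of cells was -42.4 at 1000 UMIs or more (exact p = 0.0571) and -51.2 to -33.3 with a sample left out. Oxyphil against chief called 394 genes with DESeq2's Wald test, 866 with no count filter, 962 in the fit of all samples, and 0 to 10 with a sample left out. The macaque range called 967 with DESeq2, 1406 with count splitting and 835 to 1802 with a sample left out. The adenoma range called 210 with DESeq2, 34 at a limit of 20%, where oxyphil replicate 2 keeps 18 cells per group, 763 with doublets kept, 181 with count splitting, 1078 with PTH over all UMIs, 142 split at the median, 298 within depth bins and 41 to 536 with a sample left out. Without the replicate block that pairs cells of 1 sample, both ranges called 0, since differences between samples then count as noise. The interaction called 796 at the limit of 20%, 936 with count splitting and 843 to 1644 with a sample left out. LAMA4, PTH-range by species interaction genes, reversed to 0.26 at 1000 UMIs or more (adjusted p = 0.920). With an estimated correlation, 0 lists passed in each of the 5 comparisons. Oxyphil against chief had 3 lists passing with all cells and 3 in the fit of all samples, adenomas against macaques 4 with oxyphil adenomas alone, and the macaque range 9 with no count filter. Oxyphil replicate 2 has 30 cells per group.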
